A study of Mus musculus with 6 samples.

How the data were processed

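Gene expression was measured in mouse BCR-ABL1-driven acute lymphoblastic leukaemia cells on Affymetrix 3' expression arrays, which read each transcript with probe sets that mostly lie near its 3' end. Per the labels' protocols, total RNA was purified on RNeasy columns and 6 micrograms per sample were turned into biotinylated cRNA. The 6 arrays fall into 2 groups of 3 by their titles: leukaemia from animals lacking activation-induced cytidine deaminase (AID-/-) and leukaemia with the intact gene (AID+/+), both labelled as Balb/c. The titles call the arrays biological replicates, but nothing says whether the 3 leukaemias of a group came from separate animals, so p-values measure only the spread between these samples.

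The deposited values are log2 expression values, 1 column per array. The submitters' processing notes name RMA and Partek, without versions or the order of steps; RMA corrects background, normalises between arrays and summarises the probes of a probe set on the log2 scale. The array medians lay between 4.85 and 4.90 and the quantiles were close but not identical, so a further between-array scaling was tried as an alternative. No scanner files or detection calls were used here, so no probe set could be called absent, and values near the lower end of the scale hold little order. The number of arrays, not a read depth, limits the precision.

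Of 45101 probe sets, 64 array controls were left out and 45037 were tested. The platform annotation used here gave 34945 of these exactly 1 gene symbol and 932 several symbols, while 9160 were not named in it. Symbols were updated by Entrez identifier to RefSeq names of the GRCm38.p6 assembly, which matched 34741 probe sets. Coordinates are not printed, because no genome build is stated for the arrays. A gene was represented by its probe set with the highest mean over all 6 arrays, which gave 18193 genes, of which 9010 had more than 1 probe set.

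Differences were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, group as the only term, no filter on dim probe sets), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. They are given as AID-/- minus AID+/+ on the log2 scale with the moderated standard error (SE); group means carry the SD of 3 arrays. Adjusted p-values of single genes are over the 18193 genes. The 22 gene lists were fixed before the data were examined. Of these, 21 had at least 5 measured members and were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists. This test asks whether members shift together against all other genes. A list described below as not shifted is one that did not pass this test, which does not show that it stayed the same. The call was repeated with the correlation estimated from each list, which rests on 4 residual degrees of freedom, and with fry, which asks only whether members move one way on balance.

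The genes named in the text were chosen by a rule written before the data were examined. It takes the 12 genes with the largest difference in each direction among those past the threshold, with non-overlapping groups and a higher-group mean above the median probe set, and up to 4 members of each list with the smallest p; 1 of the tested lists is not described here. Genes named beyond that rule are marked as chosen after their values were seen.

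Same-numbered replicates did not deviate together: the correlations of their deviations from the group means were -0.05, -0.07 and 0.03, so the numbers were not treated as pairs, and the replicate block was an alternative. Other alternatives were quantile normalization, median centring, a filter on dim probe sets, moderation with an intensity trend, no moderation, array weights, other thresholds, averaging probe sets, leaving out each array in turn and, added after seeing the data, leaving out genes of chromosomes X and Y. The fit was tested on simulated data built from the means and residual spread of these 45037 probe sets with 200 changed ones. For this comparison it recovered 98.5% of changes of 2 on the log2 scale, 61.2% of changes of 1 and 4.48% of changes of 0.5, with 8 false calls. Far fewer probe sets were changed than the 6589 called in the real data. The adjusted threshold was therefore stricter in the simulation, and its recoveries may be too low for these data. The list test recovered a list of 25 genes that were all shifted by 0.5 and called 0 of 20 unshifted lists, each list drawn from 18193 genes. Few other simulated genes were changed and all members of the shifted list moved alike, unlike in the real lists. Its recovery may therefore be too high for these data. The simulated genes varied independently, whereas correlations estimated in the real lists reached 0.4547, for interferon response genes. The simulation therefore does not show how often correlated lists are called without a shift.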

Results

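Expression profiles were compared between BCR-ABL1-driven mouse leukaemias with and without activation-induced cytidine deaminase (AID), the enzyme that deaminates cytidines in immunoglobulin genes during somatic hypermutation and class switching. BCR-ABL1 is the fusion kinase of Philadelphia chromosome-positive leukaemia. The series set out to find expression differences between AID-expressing and AID-deficient leukaemia. Each group held 3 arrays, with RMA values between 2.15 and 14.33 on the log2 scale. Arrays of 1 group resembled each other closely: Pearson's r across probe sets, which are not independent replicates, was 0.991 to 0.994 within AID-/- and 0.995 to 0.996 within AID+/+, against 0.972 to 0.977 between groups. Pairs of AID-/- arrays differed by at least 1 log2 unit at 390 to 700 probe sets, pairs of AID+/+ arrays at 100 to 206, and pairs across groups at 1884 to 2543. The first principal component held 72.4% of the variance and separated the groups.

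The AID-/- and AID+/+ leukaemias differed at a large share of the measured genes. In AID-/- leukaemia, 1840 of 18193 genes were higher and 1531 were lower, and 909 genes differed by at least 2-fold, or 1 log2 unit. Differences of at least 3 log2 units were found for 121 genes, of which 96 were higher and 25 lower in AID-/- leukaemia. At the level of probe sets, limma called 6589 of 45037 at an adjusted p under 0.05, with 3262 higher and 3327 lower. An ordinary linear model without variance moderation called 2363 probe sets, and without AID+/+ replicate 3 the moderated fit called 4307. The groups did not overlap for 36.5% of genes, where chance gives 10%.

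Sex-linked transcripts separated the groups completely. Xist, the non-coding RNA that silences one X chromosome in female cells, was at 12.01 ± 0.14 (SD, n = 3) in AID+/+ and 5.30 ± 0.86 (SD, n = 3) in AID-/- leukaemia. The Y-linked genes Kdm5d, a histone demethylase, and Uty were higher in AID-/- leukaemia by 5.08 (SE 0.10) and 3.58 (SE 0.11), with adjusted p of 1.84e-07 and 1.69e-06. All 3 AID-/- arrays thus carried Y-linked signal and low Xist, and all 3 AID+/+ arrays the opposite, so sex and genotype cannot be told apart in any comparison below. Eif2s3y, also Y-linked, was at 8.85 in AID-/- replicate 1, 3.67 in replicate 2 and 2.71 in replicate 3, against 2.51 to 2.60 in the AID+/+ arrays, and did not pass the test (adjusted p = 0.264). Genes of chromosomes X and Y made up 3.22% of the called genes; 17.2% of X-linked and 18.7% of autosomal genes were called.

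The largest increases in AID-/- leukaemia were in genes close to the floor of the scale in AID+/+ leukaemia. Ubqln2, a ubiquitin-binding shuttle protein, was at 10.63 ± 0.05 in AID-/- and 3.18 ± 0.27 in AID+/+ leukaemia (SD, n = 3), a difference of 7.44 (SE 0.14), although its second-brightest probe set differed by only 0.81. Gbp2b, an interferon-inducible GTPase, was higher by 6.11 (SE 0.31), Cfap36 by 5.97 (SE 0.21), and Retreg1, a receptor for autophagy of the endoplasmic reticulum, by 5.81 (SE 0.21), with 1.98 at its other probe set. Values near the floor hold little order, so the sizes of these differences and their ranking are approximate. Dntt, the terminal transferase that adds untemplated nucleotides at V(D)J junctions, was higher by 5.60 (SE 0.78). The remaining genes of this set were Ccdc90b, Dynlt3, a dynein light chain, Slc25a24, a mitochondrial carrier, Tmem126a, Mfsd14b, Smad1, a transducer of BMP signals, and Kdm5d, with increases of 5.08 to 5.35; another bright probe set of Kdm5d differed by 1.02. All 12 passed, and the highest adjusted p was that of Dntt, 0.00230.

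The largest decreases included Xist, at 6.71 lower, and genes expressed well above the median in AID+/+ leukaemia. Gnai1, an inhibitory G protein subunit, fell by 6.56 (SE 0.14) and Hnrnpll, an RNA-binding regulator of splicing in lymphocytes, fell by 6.03 (SE 0.20). All probe sets of both genes were lower, but by differing amounts: the others of Gnai1 fell by 5.0 and 2.2, and the other of Hnrnpll fell by 6.7. Sizes and ranking are again approximate where the AID-/- value lay near the floor, as for Gnai1 at 2.96 and Slc15a2 at 3.74. Slc15a2, a peptide transporter, fell by 4.67 (SE 0.24) at 1 of its 3 probe sets. S100a4, a calcium-binding protein, fell by 4.61 (SE 0.27), and Cd44, the hyaluronan receptor, fell by 4.33 (SE 0.29), from 9.70 ± 0.06 to 5.37 ± 0.67 (SD, n = 3). Klhdc1, Akr1c13, Kctd15, Rgcc and Bmpr1a, a BMP receptor, fell by 3.88 to 4.60. Plxna2, a semaphorin co-receptor, fell by 3.69 (SE 0.85, adjusted p = 0.0202). That call was lost without AID-/- replicate 3 or without any single AID+/+ array, with an adjusted p of up to 0.0705, and with an intensity trend (adjusted p = 0.0670).

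**Figure D1:**
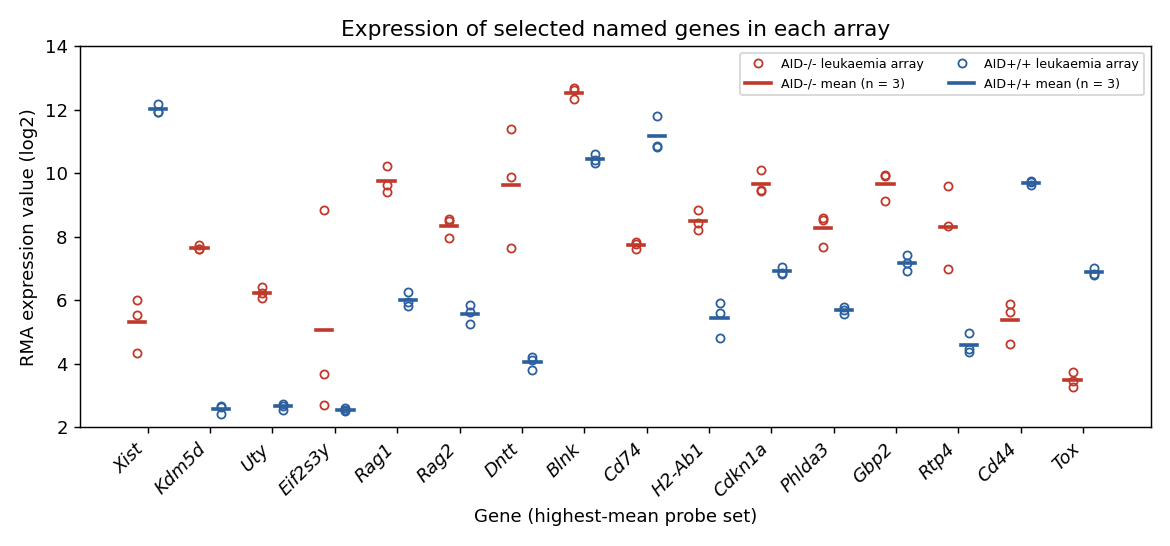
RMA expression values on the log2 scale (vertical axis) of selected genes (horizontal axis) in the 3 AID-/- arrays (red circles) and the 3 AID+/+ arrays (blue circles), with bars at the group means. Xist and the Y-linked genes Kdm5d and Uty separate the groups, Eif2s3y is high in 1 AID-/- array only, and Rag1, Rag2, Dntt, Blnk, Cdkn1a and Gbp2 lie higher in every AID-/- array than in any AID+/+ array.

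Genes of early B-lineage progenitors moved in both directions. Rag1 and Rag2, which encode the V(D)J recombinase, were higher by 3.74 (SE 0.22) and 2.78 (SE 0.20), or 13.4-fold and 6.85-fold, and Dntt was higher as above, with AID-/- arrays spread by an SD of 1.88. Cd93 fell by 0.67 (SE 0.09). Of 17 measured members 6 were higher, 3 were lower and 8 did not pass; adjusted over the list alone, 7 were higher and 3 lower. The list as a whole did not shift (camera adjusted p = 0.348).

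Among B-lineage transcription factors and surface genes, 2 of 22 were higher, 8 were lower and 12 did not pass, with the same counts adjusted over the list alone. Id3, an inhibitor of E proteins, was higher by 1.52 (SE 0.09). Cd74, the MHC class II invariant chain, fell by 3.42 (SE 0.24), Cr2, a complement receptor of mature B cells, fell by 2.09 (SE 0.22), and Bach2, a transcriptional repressor, fell by 1.77 (SE 0.19). Chosen after their values were seen, Cd22, an inhibitory receptor, fell by 2.81 (SE 0.52), Ikzf1, which encodes Ikaros, fell by 0.97 (SE 0.11), and Foxo1, an activator of the Rag genes, was higher by 1.07 (SE 0.14). The list did not shift as a whole (adjusted p = 0.348).

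Pre-B cell receptor chains stayed at high levels in both groups. Igll1, a surrogate light chain gene, was at 12.95 ± 0.14 in AID-/- and 13.14 ± 0.05 in AID+/+ leukaemia (SD, n = 3; adjusted p = 0.230), and Cd79b and Vpreb3 differed by 0.35 (SE 0.15) and 0.13 (SE 0.11) without passing. Ighm, the immunoglobulin mu heavy chain, fell by 0.86 (SE 0.18) at its brightest probe set, but its 11 probe sets disagreed and their mean differed by -0.01. It was the 1 of 7 measured members that passed, on either adjustment, and the list did not shift (adjusted p = 0.946). In the signalling list, Blnk, the adaptor downstream of the pre-B cell receptor, was higher by 2.09 (SE 0.12), or 4.26-fold. Ptpn6, which encodes the phosphatase SHP-1, fell by 1.06 (SE 0.17), with 1 of its 2 probe sets called. Pik3cd and Inpp5d were higher by 0.98 (SE 0.21) and 0.51 (SE 0.13). The call on Pik3cd was lost without AID-/- replicate 3, AID+/+ replicate 2 or AID+/+ replicate 3 (adjusted p up to 0.0599), and that on Inpp5d in 5 of 6 fits that left out 1 array, all but the one without AID-/- replicate 1 (up to 0.0910). In total 3 of its 18 members were higher, 2 were lower and 13 did not pass; adjusted over the list alone, 3 were higher and 4 lower. With 1 array left out, 1 to 4 were higher and 1 to 3 lower, and the list did not shift (adjusted p = 0.933).

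Targets of p53, the DNA damage-responsive tumour suppressor, were higher in AID-/- leukaemia as a group. Of 24 measured members, 13 were higher, 2 were lower and 9 did not pass; adjusted over the list alone, 14 were higher and 2 lower. Cdkn1a, which encodes the cell cycle inhibitor p21, was at 9.67 ± 0.37 in AID-/- and 6.92 ± 0.12 in AID+/+ leukaemia (SD, n = 3), or 6.75-fold higher. Phlda3, a repressor of AKT, was higher by 2.58 (SE 0.23), Pmaip1, which encodes the pro-apoptotic protein NOXA, by 1.68 (SE 0.15), and the death receptor gene Fas by 1.35 (SE 0.11). The lower members, chosen after their values were seen, were Sesn2 (fell by 0.77, SE 0.15) and Rrm2b (fell by 0.38, SE 0.09), but of the 4 probe sets of Rrm2b 2 were lower and 2 were higher. The call on Rrm2b was lost without AID-/- replicate 2 or 3 or AID+/+ replicate 2 or 3 (adjusted p up to 0.0910). The median difference of the list was 0.63, and camera gave an adjusted p of 1.72e-06 (adjusted p = 0.220 with an estimated correlation). The correlation estimated for this list was 0.028, near the preset 0.01. With estimated correlations, which rest on 4 residual degrees of freedom, 0 of the 21 tested lists passed.

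Interferon response genes were also higher in AID-/- leukaemia, with 14 of 27 measured members higher, 0 lower and 13 not passing; adjusted over the list alone, 15 were higher and 0 lower. The guanylate-binding protein gene Gbp3 was higher by 1.96 (SE 0.12), and Gbp2 was 5.64-fold higher, at 9.66 ± 0.47 in AID-/- and 7.17 ± 0.25 in AID+/+ leukaemia (SD, n = 3). Ifih1, a cytosolic sensor of viral RNA, was higher by 1.56 (SE 0.17), and Ifit3 by 1.53 (SE 0.21). The median difference was 0.88, and camera gave an adjusted p of 2.96e-08 (adjusted p = 0.912 with an estimated correlation). The list did not pass with fry either (adjusted p = 0.0677). Random lists matched on expression, a test run after the list had passed, gave medians of -0.145 to 0.0789 in their middle 95%. Their members were drawn independently, so they do not answer for the correlation between members of the real list. In this list the AID-/- arrays were uneven: without AID-/- replicate 2 the median was 0.602, and without replicate 1 it was 1.06.

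Antigen presentation genes moved in opposite directions. H2-Ab1, the class II A beta chain, was higher by 3.06 (SE 0.28), at each of its 3 probe sets. Whether these probe sets read a sequence difference in place of a change in expression was not tested. The other class II genes named by the rule were lower: H2-Ea fell by 0.87 (SE 0.14) and H2-DMb2 by 0.66 (SE 0.10), beside the decrease of Cd74. The other probe sets of H2-Ea differed by -2.63 and 0.09. H2-Aa, the partner chain of H2-Ab1, and H2-Eb1, both chosen after their values were seen, fell by 1.40 (SE 0.35) and 1.07 (SE 0.18), while H2-Ob, chosen likewise, was higher by 0.59 (SE 0.12). At its brightest probe set, the call on H2-Aa was lost without any single AID+/+ array (adjusted p up to 0.0867). The other probe sets of H2-Aa differed by -2.25, -0.80 and -0.08. With probe sets averaged, H2-Aa fell by 1.13 (limma adjusted p = 0.00642). The call on H2-Ob was lost without AID+/+ replicate 3 (adjusted p = 0.0534). Of 19 members 5 were higher, 6 were lower and 8 did not pass; adjusted over the list alone, 7 were higher and 6 lower. With 1 array left out, 1 to 8 were higher. The list did not shift (adjusted p = 0.933).

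**Figure D2:**
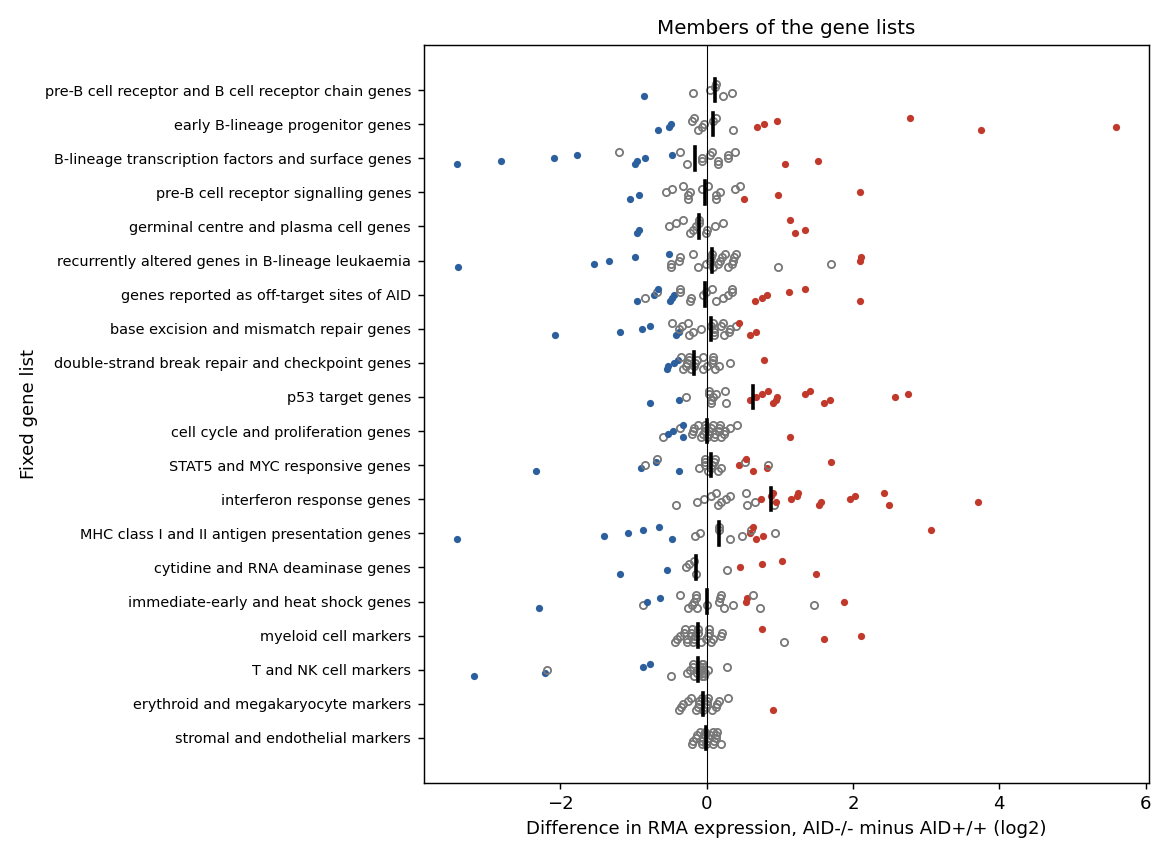
Difference in RMA expression, AID-/- minus AID+/+ on the log2 scale (horizontal axis), of every measured member of the gene lists described here (vertical axis). Filled red and blue points are members past an adjusted p of 0.05 that were higher or lower in AID-/- leukaemia, open points did not pass, and black bars mark list medians, which are 0.63 for p53 targets and 0.88 for interferon response genes.

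Genes recurrently altered in B-lineage leukaemia included 2 of 29 that were higher, 5 that were lower and 22 that did not pass; adjusted over the list alone, 8 were higher and 7 lower, and with 1 array left out 2 to 7 were higher and 4 to 7 lower. Besides Blnk, Tox, a nuclear factor of lymphocyte development, fell by 3.40 (SE 0.13) to near the floor, Nr3c1, the glucocorticoid receptor gene, fell by 1.54 (SE 0.09), or 2.91-fold, and Fhit fell by 1.34 (SE 0.13). The second higher member was Cdkn2b, chosen after its values were seen, a cell cycle inhibitor gene at 6.33 ± 0.51 in AID-/- and 4.22 ± 0.12 in AID+/+ leukaemia (SD, n = 3). Genes reported as off-target sites of AID split evenly, with 6 of 26 higher, 6 lower and 14 not passing (7 higher and 9 lower adjusted over the list alone). The called members made up a larger share of this list than the 18.5% called over all genes. Whether that excess goes beyond genes at similar expression levels was not tested. Blnk, Fas and Rhoh, a GTPase of haematopoietic cells higher by 1.12 (SE 0.12), were among the higher ones, and Cd93 was among the lower ones. Neither list shifted one way as a whole (camera adjusted p = 0.933 for both), a test that does not count changes in both directions.

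A minority of DNA repair genes passed, and they went in both directions. In base excision and mismatch repair, 3 of 27 were higher, 6 were lower and 18 did not pass (5 higher and 8 lower adjusted over the list alone; 0 to 5 higher and 3 to 6 lower with 1 array left out). Mbd4, a thymine glycosylase, fell by 2.07 (SE 0.32), Msh3, a mismatch recognition protein, fell by 1.18 (SE 0.12) at 1 of its 4 probe sets, the glycosylase gene Neil3 fell by 0.77 (SE 0.11), and Lig3, a DNA ligase, was higher by 0.59 (SE 0.13). With probe sets averaged, Mbd4 fell by 1.01 and did not pass (adjusted p = 0.0533), and the call on Lig3 was lost without AID+/+ replicate 1 or 3 (adjusted p up to 0.0532). In double-strand break repair, 1 of 24 was higher, 4 were lower and 19 did not pass (1 higher and 8 lower adjusted over the list alone). Xrcc6, which encodes Ku70, was higher by 0.79 (SE 0.13), the checkpoint kinase gene Atr fell by 0.53 (SE 0.11), Rad52 fell by 0.54 (SE 0.11) and the histone variant gene H2ax fell by 0.45 (SE 0.11). Xrcc6 and Rad52 were each called at 1 of their 2 probe sets. Atr did not pass without AID+/+ replicate 3, Rad52 without AID-/- replicate 3 or AID+/+ replicate 1, and H2ax without AID-/- replicate 1 or AID+/+ replicate 1 or 2 (adjusted p up to 0.0512, 0.0518 and 0.0849). The lists did not pass camera (adjusted p = 0.933 and 0.263). The double-strand break repair list leaned lower, with a median of -0.17. Its adjusted p was 0.0989 by camera with quantile normalization and 0.0874 by fry, so a shift is not excluded.

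Proliferation genes were close between the groups. The list held 1 higher member, 4 lower members and 26 of 31 that did not pass (1 higher and 2 lower adjusted over the list alone), with a median of 0.00 and an adjusted p of 0.985. Ube2c, an E2 enzyme of mitotic exit, was higher by 1.14 (SE 0.12), the phosphatase gene Cdc25c fell by 0.46 (SE 0.08), the thymidine kinase gene Tk1 fell by 0.53 (SE 0.10) and the checkpoint gene Bub1b fell by 0.32 (SE 0.09), a call that was lost whichever array was left out (adjusted p up to 0.111). Among STAT5 and MYC responsive genes, 5 of 24 were higher, 4 were lower and 15 did not pass (5 and 5 adjusted over the list alone; 3 to 5 higher with 1 array left out; list adjusted p = 0.933). The kinase gene Pim1 and the cytokine-signalling inhibitor Cish were higher by 0.83 (SE 0.13) and 0.63 (SE 0.11), while Socs2 fell by 0.90 (SE 0.11) and the hexokinase gene Hk2 fell by 0.69 (SE 0.10). Ccnd2, which encodes cyclin D2, was chosen after its values were seen and fell by 2.34 (SE 0.43).

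Germinal centre and plasma cell genes included 3 of 17 that were higher, 2 that were lower and 12 that did not pass (3 and 4 adjusted over the list alone; 1 to 3 higher with 1 array left out; list adjusted p = 0.933). Beside Fas, Xbp1, a factor of the unfolded protein response, was higher by 1.14 (SE 0.25), a call lost without AID+/+ replicate 1 or 2 (adjusted p up to 0.0672). Irf4 and Tnfrsf13b, which encodes the receptor TACI, fell by 0.95 (SE 0.13) and 0.93 (SE 0.16). In the deaminase list 4 of 11 were higher, 2 were lower and 5 did not pass, on both adjustments (list adjusted p = 0.933). Ada, which encodes adenosine deaminase, was higher by 1.49 (SE 0.12) and Samhd1, a dNTP hydrolase, by 1.02 (SE 0.18), while Apobec3, a cytidine deaminase that restricts retroviruses, fell by 1.18 (SE 0.18), and Apobec2 fell by 0.54 (SE 0.10) at 1 of its 2 probe sets (mean of both -0.17, adjusted p = 0.247). Samhd1 was called at 2 of its 5 probe sets.

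Markers of other cell types were mostly low and close between the groups. T and NK cell markers shifted lower in AID-/- leukaemia (camera adjusted p = 0.0471; adjusted p = 0.912 with an estimated correlation), with 0 of 24 higher, 4 lower and 20 not passing (0 and 5 adjusted over the list alone). The list's median of -0.11 lay inside the middle 95% of random lists matched on expression, -0.127 to 0.0306, a test run after the list had passed. The 4 were Gzmb, a cytotoxic granule protease, which fell by 3.18 (SE 0.49), Lat, an adaptor of T cell receptor signalling, which fell by 2.21 (SE 0.48), Klrd1, a natural killer receptor gene, which fell by 0.87 (SE 0.15), and Cd28, which fell by 0.77 (SE 0.20). Klrd1 and Cd28 lay near the floor of the scale in both groups. The T cell receptor component genes Cd3e and Cd3d, chosen after their values were seen, differed by -0.05 and -0.13 without passing. The list's call was lost without AID+/+ replicate 2 (adjusted p = 0.182) or 3 (adjusted p = 0.0894). It was also lost with quantile normalization (camera adjusted p = 0.0837), with bright probe sets only (camera adjusted p = 0.273) and with fry (adjusted p = 0.0677). Lat did not pass without AID+/+ replicate 1 or 3, nor Cd28 without AID-/- replicate 1 or 3 or AID+/+ replicate 2 or 3 (adjusted p up to 0.0587 and 0.0962). Lat was also lost with an intensity trend (adjusted p = 0.0515) and Cd28 with probe sets averaged (adjusted p = 0.0601).

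Of the myeloid markers 3 of 28 were higher, 0 were lower and 25 did not pass (2 and 0 adjusted over the list alone; list adjusted p = 0.933). The Fc receptor gene Fcgr3 was higher by 2.11 (SE 0.24), and the lysozyme genes Lyz1 and Lyz2 by 1.60 (SE 0.29) and 0.76 (SE 0.21). Lyz2 passed in 1 of 6 fits that left out an array, the one without AID-/- replicate 3 (adjusted p up to 0.135), and the fourth member named, Csf1r, differed by -0.30 without passing. The abundant neutrophil gene S100a8, chosen after its values were seen, was at 3.14 in AID-/- and 3.35 in AID+/+ leukaemia. Among erythroid and megakaryocyte markers, Tfrc, the transferrin receptor gene, was higher by 0.91 (SE 0.16), while Epor, Pf4 and Gata1 differed by -0.36, -0.38 and -0.33 without passing, as did the other members (1 higher of 21 on both adjustments; list adjusted p = 0.933). None of 21 stromal and endothelial markers passed in limma, and their collagen and decorin genes Col3a1, Col1a2, Dcn and Col1a1 differed by -0.19, -0.21, 0.14 and -0.13 (list adjusted p = 0.946). Immediate-early and heat shock genes, a sign of handling stress, included 3 of 23 that were higher, 3 that were lower and 17 that did not pass, on both adjustments (list adjusted p = 0.933). Jun and the chaperone gene Hsph1 were higher by 1.87 (SE 0.35) and 0.54 (SE 0.08), and Nr4a1 and Atf3 fell by 0.64 (SE 0.09) and 0.81 (SE 0.13).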

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

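The number of called probe sets, 6589 (3262 higher and 3327 lower in AID-/- leukaemia), moved by over 1.5 times under an ordinary linear model (2363, 1209 higher and 1154 lower), with a required log2 difference of 1 (1786, 1014 and 772), when genes were counted in place of probe sets (3371, 1840 and 1531), and without AID+/+ replicate 3. Leaving out each array in turn gave 4307 to 6109 calls, 2091 to 3198 higher and 2216 to 2911 lower; the lowest total, without AID+/+ replicate 3, shared 4197 calls with the fit on all arrays. Median centring gave 3589 higher and 2937 lower, so which direction was more frequent depended on the scaling. The ordinary model has only 4 degrees of freedom for each variance, and fewer arrays or fewer units give fewer calls by construction. The replicate block gave 5369 calls, of which 5145 were shared in the same direction. Among the genes named in the text it ended the calls on H2ax (adjusted p = 0.0750), Bub1b (0.103), Rrm2b (0.0740) and H2-Aa (0.0668), and it ended no list call. Leaving out genes of chromosomes X and Y, chosen after seeing the data, gave 6390. With 1 array left out, 1 to 8 antigen presentation genes, 2 to 7 recurrently altered leukaemia genes, 0 to 5 base excision and mismatch repair genes, 1 to 4 pre-B cell receptor signalling genes, 1 to 3 germinal centre and plasma cell genes and 3 to 5 STAT5 and MYC responsive genes were higher, and 1 to 3 pre-B cell receptor signalling genes, 1 to 3 double-strand break repair genes, 2 cell cycle genes, 2 to 5 T and NK cell markers and 1 to 2 p53 targets were lower, against 12 to 13 higher p53 targets. The 4 lower double-strand break repair genes became 7 with bright probe sets only, 6 with quantile normalization and 2 with the replicate block. The p53 target list passed under every alternative run except an estimated correlation (adjusted p = 0.220). Interferon response genes did not pass with an estimated correlation (0.912) or with fry (0.0677). T and NK cell markers did not pass with quantile normalization (0.0837), bright probe sets only (0.273), an estimated correlation (0.912) or fry (0.0677), and ranged from 0.00473 to 0.182 over the fits that left out 1 array. The cause of these list changes was not tested. An intensity trend ended the calls on Plxna2 (0.0670), Lat (0.0515) and H2-Aa (0.0530), averaging probe sets ended those on Ighm, Mbd4, Bub1b, Apobec2 and Cd28 (0.0601), and median centring ended that on Bub1b (0.0585). No called list changed direction. Among called genes named in the text only Rrm2b did, at 0.13 with probe sets averaged, where it did not pass (0.474); a result past the threshold in neither fit was counted as unchanged even where its sign differed. Of the 90 called genes chosen by the rule, 77 passed in all 6 fits that left out an array. With 3 arrays per group, small differences that did not pass are not shown to be absent. Likewise, a list that did not pass is not shown to be without a shift. The simulation recovered 61.2% of changes of 1 log2 unit and 4.48% of changes of 0.5. It held only 200 changed probe sets, against 6589 called here, so it may understate the recovery.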

Other observations

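The tests on the sex chromosomes and on handling stress, and the count of genes without another bright probe set, were chosen only after the results were seen, as was leaving out genes of chromosomes X and Y. The median of the p53 list, and the sign of other probe sets of genes, had been seen before the tests on them below were run. Immunoglobulin variable gene probe sets, which no fixed list held, differed within and between groups. Of 20 probe sets naming 1 variable gene, 6 were higher and 1 was lower in AID-/- leukaemia by limma, with p adjusted over the 45037 probe sets here. Ighv14-2 was between 9.36 and 9.93 in the AID+/+ arrays and at 7.44, 5.83 and 7.24 in AID-/- replicates 1, 2 and 3 (adjusted p = 0.00223). Iglv1 was at 5.56, 7.63 and 7.40 in the AID-/- arrays, against 4.33 to 4.77 in AID+/+ (adjusted p = 0.0120 at its brightest probe set). Its other probe sets differed by -0.12 and -0.06 without passing. Igkv8-30 was at 10.10, 9.98 and 9.54, against 8.49 to 9.27. Related variable genes share sequence, so these probe sets do not name single segments with certainty.

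Within the AID-/- group, Dntt and Eif2s3y spread by SDs of 1.88 and 3.30, and Plxna2 by 2.06, where the AID+/+ SDs were 0.21, 0.04 and 0.11. The 9 probe sets of H2-D1, a class I gene that is polymorphic between mouse strains, fell into 4 that were higher in AID-/- leukaemia, by up to 1.49, and others near 0, down to -0.16.

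The first pattern is the size of the difference between groups. The real grouping gave 6589 probe sets and the highest of the other splits gave 0; with 1 of 10 splits as large, the splits are too few for a share under 0.05. For the 3 gene lists past the threshold, the highest other split gave 5 lists. Counting the real split itself, 3 of 10 splits gave at least as many, so list calls at the preset correlation also arise between mixed groups. Each mixed side held 2 arrays of 1 group and 1 of the other, so a part of the group difference remained. Lists called there may carry that part and do not show how often lists are called without a difference. The rest of the group difference adds to the spread within each side, so the 0 probe sets there do not measure chance either. X- and Y-linked genes held 3.218% of the called genes. Only 617 X-linked and 9 Y-linked genes were measured, against 3248 called autosomal genes. They could therefore not have been the bulk of the difference, and this test was settled in advance. An effect of sex on autosomal genes cannot be told apart from genotype, because all 6 arrays have Xist and Y-linked levels that go with their group, and the origin of each leukaemia (separate animals or related cells) also stays open, as does AID itself.

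The second pattern is the set of 121 genes that differed by at least 3 log2 units, many of them near the floor in 1 group. Sequence differences under single probe sets are argued against for the 56 genes with another bright probe set as a group: that probe set moved by a median of 0.8345 of the representative one's difference (bootstrap 95% interval 0.596 to 0.984). They stay open for the 7 of these with a ratio under 0.25, which include Ubqln2 and 3 genes whose other probe set had the opposite sign. They also stay open for the other 65 genes, in which no second bright probe set could be compared. The median does not speak for each gene, and sequence differences that touch several probe sets of a gene were not tested. Segments of chromosome that differ between the leukaemias may account for a part of the set. In 3 neighbouring pairs of measured genes both reached this size with the same sign, against a mean of 0.546 in 10000 shuffles of gene order (share as large 0.0176). The pairs Rasal2 with 2810025M15Rik, Gm8369 with Ms4a6b, and Pxylp1 with Spsb4 hold few of the 121 genes. The test sees only such direct neighbours, so it does not bound the part, and shared regulation of neighbours was not tested.

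The third pattern is the higher level of p53 targets in AID-/- leukaemia, a list call that camera did not give with an estimated correlation (adjusted p = 0.220). The estimate itself, 0.028, was near the preset 0.01, and 0 of the 21 tested lists passed in that mode. An intensity-dependent shift of the arrays is argued against: the list's median of 0.63 lay at percentile 100 of 10000 random lists matched on mean expression, whose middle 95% ran from -0.141 to 0.129. Handling stress stays open: 13.04% of immediate-early and heat shock genes were called higher (exact binomial 95% interval 2.78% to 33.6%). A member that did not pass is not shown to be unchanged, and members went both ways, with Jun 3.66-fold higher. No link of the p53 targets to AID, to sex or to the history of these particular cells was tested, and the design cannot separate these.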
